A study of Homo sapiens with 6 samples.

How the data were processed

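RNA sequencing had been carried out on 6 libraries of MOLP-8 cells, 3 carrying a scrambled control guide and 3 a guide against LIN28B. Per the labels' protocols, cells were grown in RPMI with serum and selected with puromycin, total RNA was extracted with a column kit, and libraries were made with a NEBNext RNA kit. Strand, poly(A) selection, read length and read numbers are not given in the sources used here. Groups were taken from the condition label of each sample and replicate numbers from the titles.

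Per the submitters' processing notes, cutadapt, TopHat2 and HTSeq were used with the GRCh37 build, with no versions and no roles given. Per the file headers, the deposited values are FPKM, fragment numbers scaled to transcript length and library size, 1 value per gene with a lower and an upper bound and a status. The file names say RPKM, and the header has the column layout of Cufflinks gene tracking files; the tool that wrote the tables and its gene annotation are not given in the sources used here. Each table had 58000 rows for 57886 genes. The 222 rows of 108 genes listed in more than 1 row were summed per gene. The 25 genes whose estimate had failed in at least 1 library, among them NDUFS1, EEF1B2 and TFRC, were left out, which kept 57861 genes. Of 13 protein-coding mitochondrial genes, 10 were listed at 0 in every library, so that an exact 0 can be a failed or suppressed estimate and not an absent transcript. Loci are those of the files, converted to 1-based starts.

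The files hold no read numbers. The deposited upper bound lies 2 SDs above the estimate, and for low genes of a single isoform the square of 2 FPKM over the distance to that bound came out whole, within 0.01, for 1238 genes in all 6 libraries at up to 50 fragments. The FPKM of 1 fragment in these genes gave relative depths of 1, 0.718 and 0.814 for control libraries 1 to 3 and of 0.638, 0.533 and 0.717 for LIN28B KO libraries 1 to 3, against control library 1. The sum of this measure over genes gave the fragment equivalents, which are estimates used to describe depth only and not for any test. Bounds cover counting error only, and reads without molecular identifiers are not independent molecules.

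The design fixed before the data were examined gave 1 test for read numbers and 1 for RPKM, and the latter applied. Log2(FPKM + 0.5) was tested with limma 3.58.1 (R 4.3.3) with a variance trend, without covariates, on 15803 genes with FPKM of at least 1 in at least 3 libraries, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The 24 gene lists were fixed before the data were examined. Lists with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01, two-sided, and again with an estimated correlation and with fry. With all 6 libraries p-values were adjusted over 22 lists. Without LIN28B KO library 3 the T and NK cell list had fewer than 3 tested members, and p-values were adjusted over the remaining lists. Counts of members are given over all genes and adjusted over the list alone. The let-7 target list of 88 genes was written from general knowledge and shares 11 genes with other lists. For let-7 sites, the longest 3′ UTR per gene among protein-coding transcripts of GENCODE 29 was used for sequence only, without coordinates, since its build differs from that of the files. Of 11434 tested protein-coding genes, 11309 (98.9%) had such a UTR; of all 15803 tested genes 71.6% did, the rest being mostly non-coding. The difference of medians was set against permutations within 5 classes of UTR length by 5 classes of mean expression.

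Genes named in the text followed a rule fixed before the data were examined: LIN28B and LIN28A, the 10 largest rises and falls and the 5 smallest p in each direction among called genes with a symbol, a mean of at least 1 FPKM and non-overlapping groups, up to 4 members per list by p, and 9 let-7 or MYC genes whatever their p; some genes that the rule picks are not reported here. Immunoglobulin and T cell receptor segments were passed over. The same rule was applied to the 5-library fit, which was added after the data were seen and used the 11308 genes that GENCODE 29 lists as protein-coding under the same identifier and that passed the filter without LIN28B KO library 3. Of the 15803 genes tested with all 6 libraries, 840 had no match there.

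The scripts were tested on simulated data with 200 changed genes. With 6 libraries and 15803 genes, 0%, 40%, 92% and 98% of genes changed by a log2 fold of 0.5, 1, 2 and 3 were recovered with 5 false calls; in the 5-library fit with 11308 genes, 62%, 90%, 96% and 100% were recovered with 9 false calls. Camera found a list shifted in the simulation and not an unshifted one. The site test, run on 11311 genes, returned -0.20 for a simulated shift of -0.2. The simulated values did not depend on UTR length or expression, so the matching on these was not tested. The simulated shift was also larger than the excess found in the data.

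Alternatives planned before the data were examined were leaving out each library, the replicate number as a block, no filter, a filter at FPKM of at least 5, pseudocounts of 0.1 and 1, quantile normalization, median centring and other thresholds. Those planned for read numbers could not be run because the files hold FPKM only. Alternatives added after the data were seen were cyclic loess, array weights, protein-coding genes only, and combinations of these with LIN28B KO library 3 left out. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9 was used for the rest.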

Results

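Transcriptomes of MOLP-8, an established human multiple myeloma cell line, were measured by RNA sequencing after lentiviral CRISPR targeting of LIN28B. LIN28B is an RNA-binding protein that blocks maturation of the let-7 family of microRNAs, and let-7 in turn represses mRNAs that carry matching sites in their 3′ UTRs. Control cells received a scrambled guide and LIN28B KO cells a guide against LIN28B, both in the lentiCRISPRv2 vector, and cells were selected with puromycin. Each group had 3 libraries, 6 in all. The question set by the design is which transcripts differ when LIN28B is targeted, and whether those governed by the LIN28B/let-7 axis are among them. Nothing in the labels says whether the 3 libraries of a group came from separate cultures or transductions, so p-values measure only the spread between these libraries, which may be technical.

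The deposited values were FPKM per gene, with 57861 genes usable in every library. Fragment equivalents, estimated from the deposited bounds, came to 8363369, 6314994 and 7081937 for control libraries 1 to 3 and to 5603487, 4813381 and 4914475 for LIN28B KO libraries 1 to 3. Genes with FPKM of at least 1 numbered 15450, 15386 and 15375 in the controls, 15950 and 15939 in LIN28B KO libraries 1 and 2, and 17694 in LIN28B KO library 3.

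LIN28B KO library 3 stood apart from the other 5 libraries. Among 401 olfactory receptor genes, which are not expected in blood-lineage cells, 30.4% had a value above 0 in that library, against 10.2% to 13.0% in the controls and 11.7% and 14.5% in LIN28B KO libraries 1 and 2. MALAT1, a nuclear long non-coding RNA, stood at 892 FPKM there, at 314 and 331 FPKM in LIN28B KO libraries 1 and 2 and at 259.3 to 286 FPKM in the controls. NEAT1, another nuclear RNA, was not higher in it, at 311 FPKM against 459 and 452 FPKM in LIN28B KO libraries 1 and 2. Abundant mRNAs were lower in it: ACTB, cytoplasmic actin, was at 1290 FPKM against 1888 and 1930 FPKM. For protein-coding genes with a control mean of 20 to 100 FPKM, the median log2 ratio to the control mean was -0.50 in library 3 and -0.07 in each of libraries 1 and 2. Over all tested genes the median log2 fold change of LIN28B KO against control was -0.13 with all 6 libraries and 0.00 after cyclic loess scaling, so list medians below are set beside the median of all genes. A second comparison was therefore run on the protein-coding genes without LIN28B KO library 3, a choice made after these values had been seen. It is called the 5-library fit here, and its median was -0.04.

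**Figure D1:**
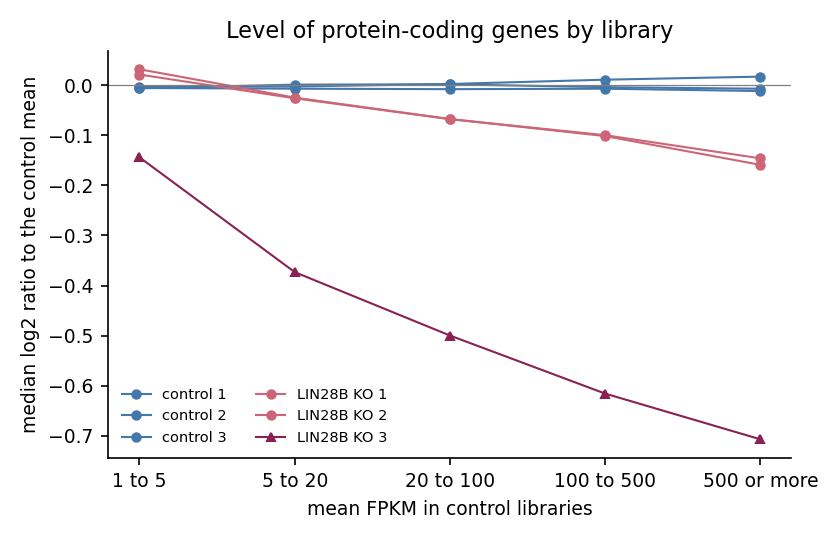
Median log2 ratio of FPKM to the control mean (vertical axis) for protein-coding genes in 5 classes of mean control FPKM (horizontal axis), 1 line per library. LIN28B KO library 3 runs from -0.14 in the lowest class to -0.71 in the highest, while LIN28B KO libraries 1 and 2 stay between 0.03 and -0.16.

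LIN28B itself was the first gene examined. It lies on chromosome 6 at 105404923 to 105531207 of GRCh37 (gene ENSG00000187772; the deposited locus of the whole gene). Its level was 23.3, 24.3 and 25.5 FPKM in the controls and 8.41, 8.17 and 5.84 FPKM in the LIN28B KO libraries. The means were 24.4 ± 1.07 FPKM (SD, n = 3) and 7.47 ± 1.42 FPKM (SD, n = 3), so that LIN28B KO cells kept 30.7% of the control mean, a 3.26-fold lower level. The deposited bounds, which cover counting error only, ran from 22.5 to 24.2 FPKM in control library 1 and from 5.29 to 6.40 FPKM in LIN28B KO library 3. An exact two-sided permutation test of 3 against 3 values gave p = 0.1, the smallest p that this design allows. In the limma fit across all genes the log2 fold change was -1.66 (SE 0.17, adjusted p = 0.0207). The call was lost when any 1 library other than LIN28B KO library 3 was left out (adjusted p up to 0.185). Without LIN28B KO library 3 the remaining KO libraries held 34.0% of the control mean, and the 5-library fit gave -1.50 (SE 0.09, adjusted p = 0.00749). The paralog LIN28A was barely detected, at 0.140 ± 0.0311 FPKM (SD, n = 3) in control and 0.655 ± 0.479 FPKM (SD, n = 3) in LIN28B KO, with 1.21 FPKM in library 3, and was under the filter.

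**Figure D2:**
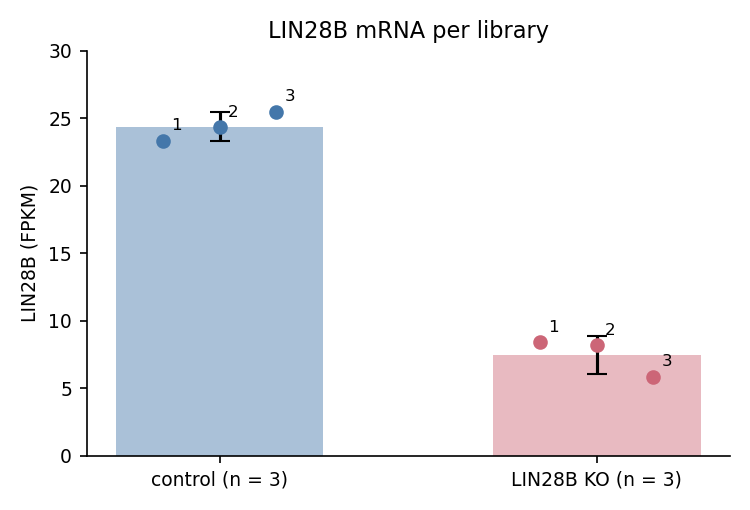
LIN28B level in FPKM (vertical axis, from 0) in control and LIN28B KO cells. Points are libraries with their numbers, bars are means and error bars are SDs (n = 3 per group); the 3 control libraries lie between 23.3 and 25.5 and the 3 KO libraries between 5.84 and 8.41.

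With all 6 libraries, limma called 10 genes higher and 5 lower in LIN28B KO cells among 15803 tested (Benjamini-Hochberg adjusted p under 0.05), while 2163 genes had an unadjusted p under 0.05. LIN28B was the only called gene with a measurable level in both groups. The other 14 were listed at 0 in every library of 1 group, and nearly all were unnamed clone models or pseudogenes. MIR92B, the precursor of a microRNA, was listed at 0 in the 3 controls and at 10.0, 12.1 and 17.4 FPKM in the KO libraries. The pseudogene POLR2KP1 was listed at 0 in the controls and at 2.79, 3.36 and 5.04 FPKM in the KO libraries, and the pseudogene MTATP8P2 at 1.82, 2.54 and 2.20 FPKM in the controls and at 0 in the KO libraries. Short models and pseudogenes share sequence with other genes, so their values are uncertain. Quantile normalization gave 15 higher and 13 lower genes, and cyclic loess, which removes a trend with level and was added after seeing the data, gave 57 and 54.

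The 5-library fit called 122 genes higher and 341 lower among 11308 protein-coding genes. With cyclic loess on the same libraries the counts were 122 and 132, so the surplus of lower genes depended on the scaling; 239 of the 463 calls were shared, 107 higher and 132 lower, with 0 of opposite sign. LIN28B KO library 3, which took no part in that fit, moved in the same direction for 430 of the 463 called genes (92.9%) after cyclic loess. Simulated unchanged groups sharing the same controls gave 78.9% on average and at most 84.4%. The simulation allows for the shared controls in unchanged groups only, and the controls are too few to split. Part of the excess may therefore still come from them.

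The largest rises in the 5-library fit were in TSPAN19, C10orf11, CHURC1-FNTB, GPR56 and ABI3BP. Fold changes are on the log2(FPKM + 0.5) scale, which understates those of low genes. GPR56, an adhesion G protein-coupled receptor, was 2.91-fold higher (log2 fold change 1.54, SE 0.19, adjusted p = 0.0249), going from 2.59 FPKM in control to 8.40 FPKM. ABI3BP, an extracellular matrix protein, was 2.79-fold higher (SE 0.16 on the log2 scale), SHANK2, a synaptic scaffold, 2.66-fold (SE 0.21) and ST3GAL6, a sialyltransferase, 2.28-fold (SE 0.15). TSPAN19 and C10orf11 rose 3.11-fold (SE 0.25) and 3.09-fold (SE 0.22), and the latter reached 57.8 FPKM in LIN28B KO library 3 against 11.3 and 16.7 FPKM in libraries 1 and 2. CNTNAP3B rose 2.33-fold (SE 0.22) and has a near-identical copy, so it is uncertain; with ZNF385D and PTGES3L-AARSD1 it missed the threshold with cyclic loess on the 5 libraries (adjusted p = 0.0533, 0.0521 and 0.0533), where their log2 fold changes were 1.16 (SE 0.22), 1.34 (SE 0.25) and -1.81 (SE 0.35) against 1.22, 1.38 and -1.73. ZNF385D (2.59-fold, SE 0.25) and HDAC11, a class IV histone deacetylase (2.36-fold, SE 0.14), also passed, but in LIN28B KO library 3 they stood at 1.46 and 2.80 FPKM, not above their control means of 1.57 and 3.50 FPKM. Among the rises with the smallest p were EDNRB, an endothelin receptor, from 104 to 172 FPKM (1.65-fold, adjusted p = 0.0142), BOD1L1, which protects replication forks (1.99-fold, adjusted p = 0.0160), and FTH1, the ferritin heavy chain (1.39-fold, adjusted p = 0.0171). BOD1L1 and FTH1 were at 12.6 and 1210 FPKM in library 3, near or below their control means of 12.1 and 1442 FPKM; after cyclic loess, which removes that library's trend with level, their log2 ratios to the control mean there were 0.48 and 0.45, above all controls, and those of ZNF385D and HDAC11 were 0.08 and -0.02, within the range of the controls.

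Falls were largest, apart from LIN28B, in NT5DC4, the readthrough models named below, LTB and LRRC26. LTB, lymphotoxin beta, was 2.46-fold lower (log2 fold change -1.30, SE 0.16, adjusted p = 0.0248), from 3.66 to 1.19 FPKM. IFITM1, an interferon-induced antiviral membrane protein with close paralogs, was 2.30-fold lower (log2 fold change -1.20, SE 0.15), with 1.14 FPKM in library 3 as well. CFI, complement factor I, was 2.24-fold lower (SE 0.20), EFNA5, an ephrin ligand, 2.16-fold (SE 0.17), TRIM9, an E3 ubiquitin ligase, 2.38-fold (SE 0.17) and LRRC26, a potassium channel subunit, 2.45-fold (SE 0.17). With the smallest p among falls stood LIN28B, the histone variant H2AFZ (1.52-fold), the water and glycerol channel AQP3 (1.59-fold), CKS1B, a subunit of cyclin-dependent kinases (1.56-fold), and RRM2, the small subunit of ribonucleotide reductase (1.59-fold). All 4 of the latter had an adjusted p of 0.0142. The rule also picked CHURC1-FNTB, higher, and PTGES3L-AARSD1 and ZNF559-ZNF177, lower, which are readthrough models that share reads with their parent genes; CHURC1-FNTB and ZNF559-ZNF177 stood at 5.36 and 2.13 FPKM in LIN28B KO library 3, near their control means of 5.26 and 2.09 FPKM, and within the range of the controls after cyclic loess (log2 ratios of 0.41 and 0.08). NT5DC4 was listed at 0 in LIN28B KO libraries 1 and 2 and at 2.32 FPKM in library 3.

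**Figure D3:**
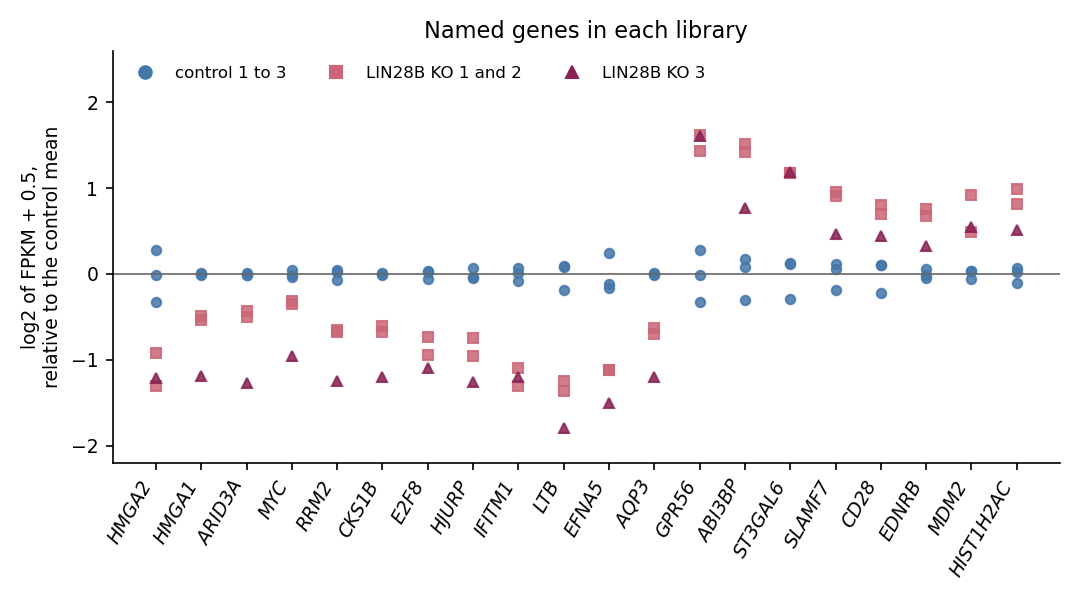
Level of 20 named genes in each library, as log2 of FPKM + 0.5 relative to the control mean (vertical axis). Circles are the 3 controls, squares LIN28B KO libraries 1 and 2 and triangles LIN28B KO library 3; HMGA2 to AQP3 lie below the controls and GPR56 to HIST1H2AC above them in all 3 KO libraries.

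Genes of the cell cycle were lower as groups in LIN28B KO cells. Of 72 G1/S genes tested, the median log2 fold change was -0.56 with all 6 libraries (limma's camera test, adjusted p = 7.94e-24 over 22 lists), and of 68 G2/M genes it was -0.53 (adjusted p = 2.33e-23). In the 5-library fit the medians were -0.49 and -0.44, and 33 of 71 G1/S genes and 34 of 68 G2/M genes fell, with none higher. Adjusted over the list alone, 61 and 58 fell. With cyclic loess on the same 5 libraries 18 and 20 fell over all genes, with medians of -0.42 and -0.40 against 0.00 for all genes. The G1/S group included E2F8, a transcription factor of the E2F family (1.79-fold lower, from 9.23 to 4.95 FPKM, adjusted p = 0.0266), CHAF1A, a subunit of the chromatin assembly factor (1.70-fold, adjusted p = 0.0249), and the DNA polymerase subunit POLD3 (1.65-fold, adjusted p = 0.0313). The G2/M group included HJURP, the chaperone of centromeric histone (1.81-fold lower, from 40.0 to 22.0 FPKM, adjusted p = 0.0198), NUF2 of the kinetochore (1.76-fold, adjusted p = 0.0226), PSRC1 of the spindle (1.86-fold, adjusted p = 0.0292) and the condensin subunit NCAPG (1.53-fold, adjusted p = 0.0249). With all 6 libraries no single member passed over all genes, although 57 and 50 did adjusted over the list alone. Both lists lost the call with all 6 libraries when the correlation was estimated (adjusted p = 0.582 and 0.687 with an estimated correlation) and kept it in the 5-library fit (adjusted p = 0.0369 and 0.0370 with an estimated correlation). LIN28B KO library 3, where abundant mRNAs were lower in general, carried the same direction.

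**Figure D4:**
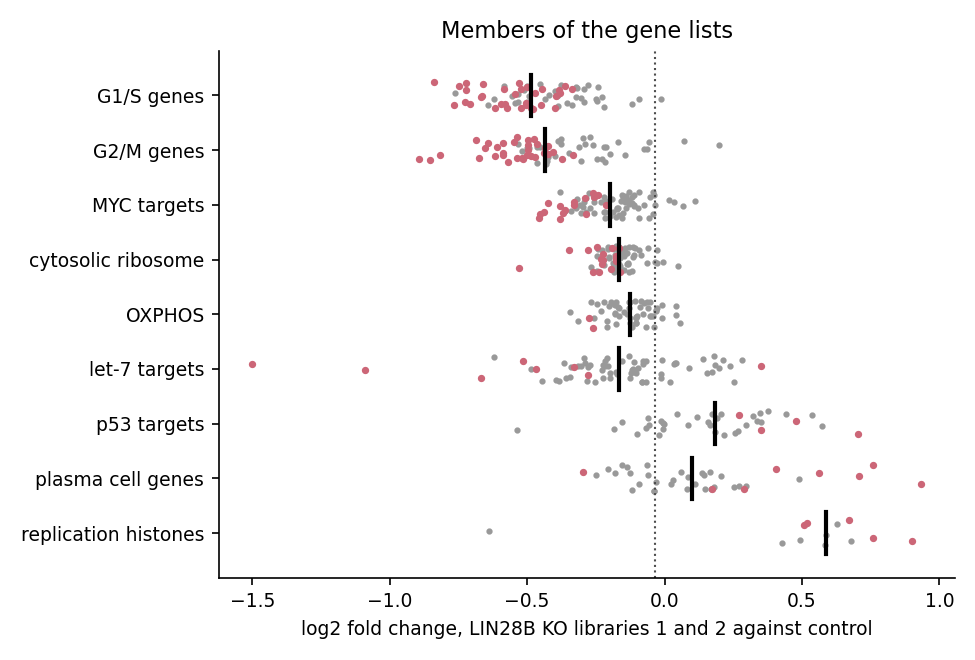
Log2 fold change of LIN28B KO libraries 1 and 2 against the 3 controls (horizontal axis) for the members of 9 gene lists (rows). Red points passed the 5-library limma fit, grey points did not, black bars are list medians and the dotted line is the median of all genes at -0.04; the G1/S median lies at -0.49 and that of replication histones at 0.59.

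MYC target genes, cytosolic ribosomal proteins and subunits of oxidative phosphorylation were also lower as groups, by less. With all 6 libraries the medians were -0.37 for 80 MYC targets (adjusted p = 4.89e-11), -0.37 for 73 ribosomal protein genes (adjusted p = 1.12e-08) and -0.32 for 56 oxidative phosphorylation genes (adjusted p = 1.92e-06). No member of the 3 lists passed over all genes, or adjusted over the list alone. In the 5-library fit the medians were -0.20, -0.17 and -0.12, and 16 of 79, 17 of 73 and 2 of 56 members fell, against 42, 56 and 5 adjusted over the list alone. With cyclic loess on the same 5 libraries these falls were mostly lost: 2, 1 and 0 members fell over all genes, 14, 1 and 0 adjusted over the list alone, and the medians were -0.11, -0.05 and -0.03. PA2G4, a nucleolar growth regulator, was 1.37-fold lower (SE 0.07 on the log2 scale), RANBP1 1.37-fold (SE 0.06) and the pre-rRNA methyltransferase FBL 1.29-fold (SE 0.05). RPL14 and RPL8, proteins of the large ribosomal subunit, were 1.44-fold and 1.21-fold lower, as were UQCRH of complex III (1.20-fold) and ATP5F1 of ATP synthase (1.21-fold); of the genes just named, FBL, RPL8, UQCRH and ATP5F1 lost the call with that scaling (adjusted p = 0.0533, 0.0693, 0.133 and 0.134), as their log2 fold changes went from -0.37, -0.28, -0.26 and -0.28 to -0.28, -0.15, -0.16 and -0.18 (SE 0.03 to 0.06). After cyclic loess, LIN28B KO library 3 lay within the range of the controls for PA2G4, RPL14 and UQCRH (log2 ratios to the control mean of 0.05, 0.02 and -0.02). It lay below all controls for RANBP1, FBL, RPL8 and ATP5F1 (log2 ratios of -0.51, -0.28, -0.17 and -0.21). Many ribosomal protein genes have processed pseudogenes, so single values are uncertain. The calls did not hold with an estimated correlation in either fit (adjusted p = 0.902 with an estimated correlation for each list with all 6 libraries, and 0.0785 for ribosomal and oxidative phosphorylation genes in the 5-library fit), except MYC targets in the 5-library fit (adjusted p = 0.0443 with an estimated correlation). The oxidative phosphorylation call was lost with cyclic loess on the 5 libraries (adjusted p = 0.0633). There the MYC target and ribosomal lists kept theirs in the camera test (adjusted p = 3.60e-10 and 3.66e-04, and 0.0220 and 0.144 with an estimated correlation). Abundant genes like these were those that lay lowest in LIN28B KO library 3.

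Genes known or predicted as let-7 targets were lower as a group. The median of 71 tested members was -0.24 with all 6 libraries (adjusted p = 9.82e-05), against -0.13 for all genes, and it was -0.16 for 70 members in the 5-library fit (adjusted p = 6.56e-04). In that fit 7 members fell and 1 rose, and 12 fell and 1 rose adjusted over the list alone. HMGA2, a chromatin protein and a classical let-7 target, was 2.13-fold lower (log2 fold change -1.09, SE 0.21, adjusted p = 0.0408), from 8.80 to 3.85 FPKM. HMGA1 was 1.43-fold lower (SE 0.05, adjusted p = 0.0142), from 260 to 182 FPKM, the transcription factor ARID3A 1.38-fold (SE 0.06, adjusted p = 0.0266) and MYC 1.26-fold (SE 0.05, adjusted p = 0.0298), from 217 to 172 FPKM. LIN28B itself, RRM2 and the histone chaperone NAP1L1 (1.21-fold, adjusted p = 0.0386) were the other falls. The member that rose was CDKN1A, a cell cycle inhibitor that is also on the p53 list (1.27-fold, adjusted p = 0.0266), although in LIN28B KO library 3 it stood at 162 FPKM against a control mean of 202 FPKM (log2 ratio of 0.29 after cyclic loess, above all controls) and with all 6 libraries its log2 fold change was 0.13 (adjusted p = 0.766). With cyclic loess on the same 5 libraries 4 members fell and 1 rose, and HMGA2 (log2 fold change -1.08, adjusted p = 0.0533), MYC (-0.24 against -0.33, adjusted p = 0.0693) and NAP1L1 (-0.18 against -0.28, adjusted p = 0.103) were past the threshold no longer. Other well-known targets did not pass in either fit. In the 5-library fit IGF2BP2 had a log2 fold change of -0.34 (SE 0.10, adjusted p = 0.106), IGF2BP3 -0.29 (SE 0.09, adjusted p = 0.132) and NRAS -0.12 (SE 0.06, adjusted p = 0.303). IGF2BP1 and CCND2 were under the filter, with control means of 0.722 and 0.0987 FPKM. With all 6 libraries LIN28B was the only member past the threshold over all genes, and 2 members passed adjusted over the list alone. The list lost the call with an estimated correlation, with all 6 libraries (adjusted p = 0.902 with an estimated correlation) and in the 5-library fit (adjusted p = 0.0864). A list of 23 proteins that make or regulate let-7, LIN28B included, had a median of -0.23 (adjusted p = 0.0154, and 0.902 with an estimated correlation); in the 5-library fit LIN28B and HNRNPA1, a let-7 precursor-binding protein (1.23-fold lower), fell among its members, HNRNPA1 lost its call with cyclic loess on those libraries (log2 fold change -0.19 against -0.30, adjusted p = 0.0677), and the list's call was lost with cyclic loess on all 6 libraries (adjusted p = 0.277) and without LIN28B KO library 2 (0.0765).

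let-7 sites were also sought in sequence. The 8-mer CTACCTCA, which pairs with the let-7 seed, occurred in the longest annotated 3′ UTR of 494 tested genes, against 10070 tested genes without the 7-mer CTACCTC. The median log2 fold change was -0.16 in both sets, a difference of 0.00. Genes matched on UTR length and expression would have differed by 0.03, so that genes with a site were lower than matched genes by a log2 difference of -0.03 (two-sided permutation test of 100000 draws, p = 0.0136). The 7-mer gave -0.02 (1241 genes, permutation p = 0.00283). Of 200 control 8-mers made of the same bases, 0 had a lower excess relative to its spread and 4 had a lower excess. The comparison is not strictly like for like. Each control 8-mer was set against all other genes, with fewer draws, and most control 8-mers occurred in fewer genes than the let-7 8-mer. Genes are not independent replicates, and the shift was small beside the change of LIN28B.

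**Figure D5:**
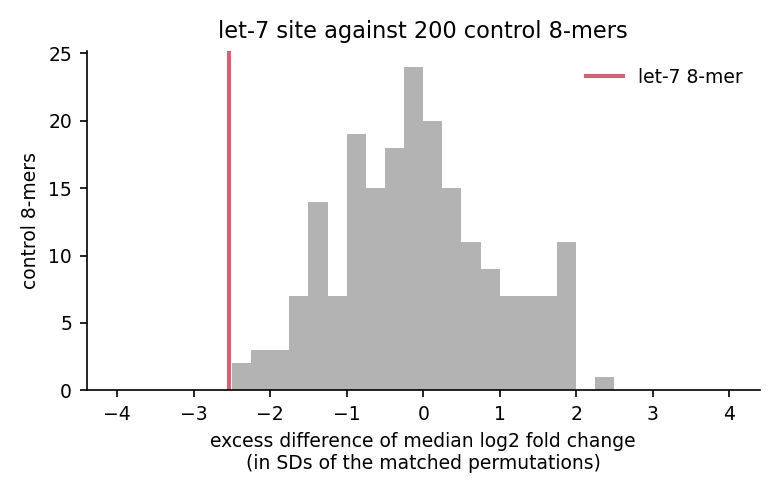
Distribution over 200 control 8-mers of the excess difference in median log2 fold change between genes with and without the 8-mer, in SDs of its matched permutations (horizontal axis), as a count of 8-mers (vertical axis). The let-7 8-mer (red line) lies at -2.54, below the lowest control at -2.47.

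Replication-dependent histone genes went the other way from the cell cycle lists. The median of 16 tested genes was 0.49 with all 6 libraries (adjusted p = 2.00e-09, and 0.404 with an estimated correlation), and that of 12 genes was 0.59 in the 5-library fit (adjusted p = 9.84e-09, and 0.0443 with an estimated correlation). In that fit 5 rose, and 11 did adjusted over the list alone. They were HIST1H2AC (1.87-fold, from 17.7 to 33.4 FPKM, adjusted p = 0.0198), HIST1H4H (1.69-fold), HIST2H2BE (1.59-fold), HIST1H2BK (1.43-fold) and the linker histone HIST1H1C (1.42-fold). In LIN28B KO library 3 HIST1H2BK and HIST1H1C stood at 37.9 and 33.8 FPKM, below their control means of 38.4 and 36.4 FPKM (log2 ratios of 0.48 and 0.39 after cyclic loess, above all controls), and HIST1H4H missed the threshold with cyclic loess on the 5 libraries (adjusted p = 0.0522) at a log2 fold change of 0.79 (SE 0.15), against 0.76 (SE 0.15) without it. Several of these genes are known to make polyadenylated transcripts as well as the usual replication-linked ones, and whether the libraries were selected for poly(A) is not given in the sources used here. Histone genes have near-identical copies, so single values are uncertain.

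The p53 target list was higher, and so was the plasma cell list in the 5-library fit and with several scalings of all 6 libraries. Of 38 p53 targets, the median was 0.04 with all 6 libraries (adjusted p = 0.0308, and 0.902 with an estimated correlation), and in the 5-library fit it was 0.19 with 4 of 37 genes higher (adjusted p = 8.19e-06, and 0.0504 with an estimated correlation). These were MDM2, the ubiquitin ligase of p53 (1.63-fold, from 221 to 364 FPKM, adjusted p = 0.0337), TP53INP1 (1.39-fold, adjusted p = 0.0386), CDKN1A and BTG2 (1.21-fold, adjusted p = 0.0442), both of which restrain proliferation. Adjusted over the list alone, 5 members rose and 1 fell. PMAIP1, of the same list, was 1.45-fold lower and did not pass over all genes (adjusted p = 0.0855). In LIN28B KO library 3 CDKN1A and BTG2 stood at 162 and 99.3 FPKM, below every control, and after cyclic loess above every control (log2 ratios of 0.29 for both). With all 6 libraries the p53 call was lost without control library 1 or 3 (adjusted p = 0.107 and 0.0535) and without LIN28B KO library 1 or 2 (0.117 and 0.127). The plasma cell list did not pass with all 6 libraries (median -0.09, adjusted p = 0.435) unless these were scaled by quantiles (0.00345), by cyclic loess (1.88e-04) or given array weights (0.0290). In the 5-library fit its median was 0.10 (adjusted p = 0.00188, and 0.183 with an estimated correlation, which became 0.0442 with cyclic loess), with 7 of 38 genes higher and 1 lower. Members went both ways when adjusted over the list alone, with 8 higher and 6 lower. With cyclic loess on the same libraries that count was 14 higher and 1 lower. SLAMF7, a surface receptor of plasma cells, was 1.91-fold higher (from 47.8 to 91.3 FPKM, adjusted p = 0.0198), the costimulatory receptor CD28 1.69-fold (adjusted p = 0.0289), CAV1, caveolin-1, 1.63-fold (adjusted p = 0.0226), the adhesion molecule NCAM1 1.47-fold (adjusted p = 0.0309) and TNFRSF17, the receptor BCMA, 1.33-fold (adjusted p = 0.0329). The integrin ITGA4 was 1.23-fold lower (adjusted p = 0.0447, and 0.0962 with cyclic loess on the 5 libraries, with log2 fold changes of -0.30 and -0.23).

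The remaining lists gave few or unstable calls. Amino acid response genes were lower with all 6 libraries (median -0.23, adjusted p = 0.0262, and 0.902 with an estimated correlation) and did not pass in the 5-library fit (adjusted p = 0.0727), in which PHGDH, SLC7A5 and SHMT2, genes of serine synthesis, amino acid uptake and one-carbon metabolism, were 1.33-fold, 1.34-fold and 1.30-fold lower (adjusted p = 0.0660, 0.0609 and 0.0533 with cyclic loess on the 5 libraries, where log2 fold changes of -0.41, -0.42 and -0.38 became -0.35, -0.36 and -0.30). Cholesterol synthesis genes passed narrowly with all 6 libraries (adjusted p = 0.0468, and 0.902 with an estimated correlation) and not in the 5-library fit (adjusted p = 0.196), nor with any 1 library but control library 3 left out (0.0508 to 0.0973). Lists for the unfolded protein response (adjusted p = 0.376), glycolysis and hypoxia (0.102), the interferon response (0.806), NF-κB (0.595), MAPK output (0.436), apoptosis (0.461), B cells (0.387), T and NK cells (0.848), fibroblasts and epithelia (0.461) and mitochondrial transcripts (0.544) did not pass with all 6 libraries. The unfolded protein response list was higher with cyclic loess on all 6 libraries (adjusted p = 5.75e-05), the reverse of its direction without that scaling. Without a filter on low values, all 6 libraries gave that list as lower (adjusted p = 9.11e-04 in the camera test). The lists for glycolysis and hypoxia (0.00176) and apoptosis (0.0133) were also called lower in that setting. Among markers of other cell types, 2 myeloid genes and 0 erythroid genes reached the filter, so these lists were not tested. ACTA2, smooth muscle actin, rose in the 5-library fit from 1.09 to 3.09 FPKM (adjusted p = 0.0313) and stood at 13.6 FPKM in LIN28B KO library 3, and KRT8, a keratin with many pseudogenes, was 1.31-fold lower (adjusted p = 0.0382, and 0.0718 with cyclic loess on the 5 libraries, with log2 fold changes of -0.38 and -0.31).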

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

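The tests in this part were chosen after the result was seen, although 1 of the settings used for the cell cycle lists, leaving out LIN28B KO library 3, had been planned. In olfactory receptor genes and intronic transcripts, LIN28B KO library 3 showed a signal above the controls: 30.4% of 401 olfactory receptor genes had a value above 0 (10.2% to 13.0% in the controls), and so did 63.2% of 133 transcripts annotated as intronic (39.8% to 47.4% in the controls). Deeper sequencing is argued against by its relative depth of 0.717 against control library 1, no higher than that of any control. Genomic DNA as the whole cause is argued against as well, since it would add the same FPKM to introns and to silent genes: over LIN28B KO libraries 1 and 2, intronic transcripts were higher by 0.717 FPKM and olfactory receptor genes by 0.0379, a difference of 0.679 (95% bootstrap interval 0.361 to 1.07). A larger share of unspliced RNA stays open and may account for part of it, as the rise of an intronic transcript followed the level of its host gene (Spearman rho = 0.325 across 133 transcripts, permutation p = 0.00015; transcripts are not independent replicates). The host gene test covers intronic transcripts only and does not bear on the olfactory receptor genes. Genomic DNA as a part of the cause was not tested and stays open as well. No biological explanation was tested, because 1 library of the group shows the pattern.

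The lower cell cycle lists were weighed next. The trend with level and LIN28B KO library 3 are argued against as the whole cause: over 6 settings that removed the trend, the library or both, the largest adjusted p of the G1/S and G2/M lists in the camera test was 3.32e-25. With cyclic loess on protein-coding genes, the G1/S median relative to all genes had a size of 0.403 in the real split of the 6 libraries and at most 0.163 in the other splits, and 1 of 10 splits, the real one, was as large. These 10 splits are too few for a share under 0.05. All but the real one mix the groups unequally and keep part of the real difference, and smaller medians in them would follow from that alone. LIN28B loss is a candidate explanation that stays open, and so is any other difference between the transduced populations, such as growth state at harvest, which was not tested: the labels name a single guide.

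For the 14 genes listed at 0 in all libraries of 1 group, unstable estimates of short or overlapping models are a candidate explanation. Genes at 0 in 3 libraries and at FPKM of at least 1 in the other 3 numbered 17 in the real split and 17 in the highest of the other splits (control library 1 with LIN28B KO libraries 1 and 3 against the rest), and 7 to 16 in the remaining ones. Such genes thus also arose between libraries parted across the groups, but whether the real grouping added to their number stays open. LIN28B, the remaining called gene, is not of this kind.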

How the results depend on the processing

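Added alternatives (cyclic loess, array weights, protein-coding genes only and settings without LIN28B KO library 3 combined with another change) were chosen after seeing the data, and where a result changed, the cause was not tested. Against 10 genes higher and 5 lower with all 6 libraries, leaving out 1 library gave 1 to 23 higher and 0 to 41 lower: 14 and 0, 13 and 0, and 17 and 0 without control library 1, 2 or 3, 1 and 6, 1 and 3, and 23 and 41 without LIN28B KO library 1, 2 or 3. Without a filter there were 5 higher and 1 lower, with the stricter filter 8 and 1, with quantile normalization 15 and 13, with median centring 7 and 3, and at adjusted p under 0.01 there were 7 and 2. Cyclic loess gave 57 and 54, array weights (0.0982 for LIN28B KO library 3 and 1.21 to 2.26 for the others) 69 and 107, and median centring without that library 22 and 42. Protein-coding genes only gave 13 and 18, with array weights 179 and 421, without LIN28B KO library 3 122 and 341, with cyclic loess 132 and 142, and with both 122 and 132. Of the 463 genes called in the 5-library fit, 396 were among the 600 called with array weights and 222 among the 274 called with cyclic loess, with 0 of opposite sign.

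For LIN28B the log2 fold change lay between -1.75 and -1.50 with 1 library left out, and between -1.75 and -1.46 over all 21 alternatives (adjusted p 2.64e-04 to 0.185). It passed in 14 of them and not with the replicate block (below), without a filter (-1.66, adjusted p = 0.142), nor with any library but LIN28B KO library 3 left out. The G1/S, G2/M, MYC and let-7 lists kept direction and call in all settings of the fit, the let-7 list with an adjusted p of at most 0.00437. They lost it with an estimated correlation (0.582, 0.687, 0.902 and 0.902) and with fry (0.0520, 0.0611, 0.248 and 0.241). The let-7 site excess lay between -0.04 and -0.02 in 12 alternatives (permutation p 4.1e-04 to 0.0251). None of these used quantile normalization, median centring, cyclic loess or array weights, and the replicate block gave the same value as the fit without it. Of the other lists, 4 of 406 values reversed, all of the unfolded protein response list, which was higher with quantile normalization (adjusted p = 0.00651), cyclic loess (5.75e-05), cyclic loess on protein-coding genes (3.01e-05) and the same without LIN28B KO library 3 (2.24e-05), while 51 became weaker and 12 stronger. Without a filter the unfolded protein response list was called lower (adjusted p = 9.11e-04 in the camera test), so it was called in both directions. Of 2278 values for named genes, 462 became stronger, 9 weaker and 0 reversed, where a change of sign counts only if a value passed. Most named genes did not pass with all libraries, and such a gene can become stronger or reverse but not weaker. Many were also picked from the fit of protein-coding genes without LIN28B KO library 3, itself an alternative. A surplus of stronger over weaker values would follow from this choice alone, so these counts do not measure stability.

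Replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at -0.02, 0.04 and -0.03, and 2 of 6 libraries correlated best with their own number. The replicate block gave 11 genes higher and 2 lower, and -1.66 for LIN28B (adjusted p = 0.0604). No alternative for read numbers (other size factors, other count tests) could be run on FPKM. At log2 fold changes of 0.5, 0% of simulated genes were recovered with 6 libraries, so smaller changes were not detectable gene by gene.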

Other observations

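The comparison with control 8-mers was planned before the values were seen, but the reading of its result was set afterwards; the other tests in this part were chosen after the values were seen, and so were the genes named here and in the next paragraph. In the 5-library fit, 4 histone genes outside the replication list were lower; other variants were not counted. H2AFX, the variant of the DNA damage response, was 1.52-fold lower (from 86.1 to 56.5 FPKM, adjusted p = 0.0188), H2AFV 1.29-fold lower (adjusted p = 0.0329, and 0.0665 with cyclic loess on the same libraries, with log2 fold changes of -0.37 and -0.30) and the linker histone H1FX 1.30-fold lower (adjusted p = 0.0289), next to H2AFZ. Proteins of the mitochondrial ribosome were lower as groups in a camera test over 122 families of genes whose symbols start with the same letters: 46 large-subunit genes (MRPL) had a median of -0.14 (adjusted p = 2.42e-04) and 28 small-subunit genes (MRPS) a median of -0.15 (adjusted p = 0.00454), with 0 members of either past the threshold. With cyclic loess on the same 5 libraries the medians were -0.08 and -0.09 (adjusted p = 0.0163 and 0.0482). Neither held with an estimated correlation (adjusted p = 0.624). Among splicing factors, SRSF1, SRSF2 and SRSF4 were 1.26-fold, 1.25-fold and 1.39-fold lower. In LIN28B KO library 3 after cyclic loess, SRSF4 lay above all controls (log2 ratio of 0.32), and SRSF1 and SRSF2 below all controls (-0.27 and -0.28). The call of the SRSF family of 11 genes (adjusted p = 0.0326) was lost with an estimated correlation (adjusted p = 0.624) and with cyclic loess on the same 5 libraries (adjusted p = 0.173), as were the calls of these 3 genes (adjusted p = 0.0845, 0.0651 and 0.0676, with log2 fold changes of -0.34, -0.32 and -0.47 before and -0.24, -0.23 and -0.40 after).

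Both ferritin chains were higher in the 5-library fit, FTH1 by 1.39-fold and FTL by 1.30-fold (from 2815 to 3655 FPKM, adjusted p = 0.0266), together with HMOX1, heme oxygenase 1 (from 5.95 to 9.60 FPKM, adjusted p = 0.0386), and the autophagy receptor SQSTM1 (1.27-fold, adjusted p = 0.0320). In LIN28B KO library 3, FTL and SQSTM1 stood at 2478 and 89.5 FPKM, below their control means, and after cyclic loess above all controls (log2 ratios of 0.55 and 0.27). Among cell cycle inhibitors CDKN1A was higher, whereas CDKN1B and CDKN2C were 1.26-fold and 1.25-fold lower (adjusted p = 0.0473 and 0.0466, and 0.0879 and 0.102 with cyclic loess on the same libraries, where log2 fold changes of -0.33 and -0.32 became -0.27 and -0.24). Among surface molecules of lymphoid cells, TNFRSF8, the receptor CD30, was 2.02-fold lower (adjusted p = 0.0347), the chemokine receptors CXCR3 and CCR2 were 1.64-fold and 1.57-fold lower (adjusted p = 0.0459 and 0.0368; CXCR3 had 0.0521 with cyclic loess, at a log2 fold change of -0.76 against -0.71), and CD48 was 1.27-fold higher (adjusted p = 0.0411). CD48 stood at 55.5 FPKM in LIN28B KO library 3, below every control, and after cyclic loess above every control (log2 ratio of 0.27). Markers of other cell types went both ways in LIN28B KO library 3, with larger rises than falls after cyclic loess among those named here. IL7R stood at 4.33 FPKM there, CD163 at 6.75, COL1A1 at 4.77 and ACTA2 at 13.6 FPKM, against highest control values of 0.404, 1.79, 1.26 and 1.26 FPKM and means of 1.14, 1.85, 1.52 and 3.09 FPKM in LIN28B KO libraries 1 and 2. From the same lists CD4 stood at 98.2 FPKM, CD7 at 0.842 and KRT8 at 69.7 FPKM, against control means of 161, 2.59 and 117 FPKM.

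One hypothesis is that let-7, released from LIN28B, may repress mRNAs with 3′ UTR sites. Of 200 control 8-mers, 0 had a lower excess relative to its spread than the let-7 8-mer with all 6 libraries, and 1 did without LIN28B KO library 3. Leaving out LIN28B and the members of the cell cycle and MYC lists gave -0.03 (permutation p = 0.00808). Of the 10 splits of the 6 libraries, 2, the real one included, gave an excess as large for its spread (2.53 in the real split, 2.65 in the highest other). The excess itself was largest in the real split (-0.0314, followed by -0.0213). These splits are too few for a share under 0.05, and all but the real one mix the groups unequally and keep part of the real difference. They cannot decide the question. The hypothesis therefore remains open. Whether the let-7 target list was lower only through LIN28B and the members of the cell cycle and MYC lists stays open. The other members gave an unadjusted p = 3.72e-04 in limma's camera test with all 6 libraries (n = 67 genes), 0.00340 in the 5-library fit (n = 66 genes) and 0.00980 with cyclic loess (n = 67 genes). With an estimated correlation the same tests gave an unadjusted p = 0.397 (n = 67 genes), 0.0527 (n = 66 genes) and 0.0292 (n = 67 genes).

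The number of calls was also set against the 10 splits of the 6 libraries, which are too few for a share under 0.05. The real split gave 15 genes and the highest other 11. For protein-coding genes with array weights the real split gave 600 genes and the highest other 5. For gene lists in the camera test, the real split gave 11 lists and the highest other 8, and each of the other splits gave at least 5, so the camera test at its preset correlation called lists in every split. The other splits mix the groups unequally, so each keeps part of the real difference, and a list called there need not be a false call. That difference also adds to the spread within their groups, and fewer calls in them would follow from that alone. In each case 1 of the 10 splits, the real one, was as large.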
